A study of Mus musculus with 9 samples.

How the data were processed

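RNA sequencing of total RNA from mouse kidney was collected for 9 libraries, 3 each of wild type (WT) and of the Nfkb1 knock-in alleles C59A and C59S, grouped by the genotype in the labels. The labels list no sex, litter or batch. Per the submitters' processing notes, total RNA was taken with TRIzol and made into libraries with the NEBNext Ultra RNA kit, and the notes list CASAVA 1.8, fastp with no version, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build GRCm38, without parameters. The counts per gene are raw whole numbers as deposited by the authors, who made them by alignment to GRCm38 and counting per the labels, with no normalization seen in the values. The deposited FPKM values, made by the authors per the file headers, equal the counts divided by gene length and by 1 constant per library, which lay between 0.802 and 1.15 times the total count. The strand setting, the annotation release and the handling of reads that map to several places were not given, so copies and paralogs may share reads.

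Both tables hold 52636 genes. Of their identifiers 52489 were in GENCODE M21, 49995 of them with the same coordinates, and 52403 had a symbol in the gene name table, 48050 of them the same. Symbols shared by several genes (99) were kept apart by identifier. All 9 sample columns were used. No pair of libraries of a genotype was a duplicate, with chi-square per degree of freedom from 24.7 to 136 between pairs. Levels are given as CPM, the counts per 1e+06 of the library total times its TMM factor (0.797 to 1.124). Total counts were 21144972, 18428728 and 18727752 in WT, 16367403, 19026934 and 23744707 in C59A, and 25787659, 20867374 and 18603933 in C59S. A floor of 3 counts corresponded to 0.112 to 0.202 CPM, below which a gene could not be told from absent.

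Genes were filtered with edgeR's filterByExpr (17114 kept), scaled with TMM factors and fitted in 1 model of all 9 libraries in R 4.3.3 with edgeR 4.0.16 (estimateDisp and glmQLFit, both robust). Each pair of genotypes, and all 3 at once, was tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and genes with adjusted p under 0.05 were called. The standard error of a log2 fold change was its size over the square root of F. Folds against groups with no reads are bounds at a floor of 3 counts over the group, and those with 1 to 3 reads are ratios of scaled reads with exact 95% counting intervals, which cover counting error only and not the spread between samples. A library order in which every library of 1 group lies above every library of the other has a chance of 10% for a gene without a change. Principal components used log2 CPM with a prior count of 2.

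A total of 42 gene lists on NF-kB signalling, immunity, matrix, transport, metabolism, stress, kidney cell types, other tissues, sex and mouse substrain were fixed before the data were examined. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 42, then again with the correlation estimated from the data, and with fry. Counts "adjusted over the list alone" adjust the edgeR p-values within the members. Of the list genes 3 were found under older symbols and 1 was not in the table. Named genes followed a rule also written before the data were examined. It took the NF-kB and Rel family, up to 10 protein-coding genes per direction with the largest fold change among called genes of at least 1 CPM with separated groups, and up to 4 genes of smallest p per list that passed or held at least 3 called genes. It also took the 5 smallest p of the test over 3 genotypes and of any comparison without calls, and the sex and substrain genes. Havcr1, Lcn2, Fabp1, Acot3, Kap, Cyp2e1, Adipoq, Cfd and the genes named by their place near Nfkb1 were named after their values were seen. Some genes that the rule takes are not reported here.

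The alternatives changed 1 choice at a time, except those on FPKM, which changed the measure, the test, the scaling and the filter together (15273 or 31298 genes tested), and the paired fit, which changed the libraries and the block. They were RLE factors, upper quartile factors or library totals alone, no filter or a stricter one (1 CPM in 3 libraries), DESeq2 1.42.0, limma voom with quality weights, no robust fit, only the 2 groups compared, and a block for the replicate number of the titles or of the sample names. Further ones left out mitochondrial genes or all but protein-coding genes, used limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 0.5 or no filter, took other thresholds, or left out each library in turn. Covariates (mitochondrial share, adipose genes, lincRNA share), leaving out C59S replicates 2 and 3, leaving out X and Y genes, and the paired fit were chosen after seeing the data. Genes within 10 Mb of Nfkb1 were compared with all others by Fisher's exact test, with 2 Mb and 30 Mb as alternatives. The pairing of libraries was checked by the correlation of their deviations from the genotype means. Libraries of WT and C59S with the same number in the titles had correlations of 0.32, 0.2 and 0.26, so these were paired in an added fit of the 6 libraries with the number as a block. The pairing comes from the data and not from the labels, which state no shared litter or day. The numbers in the sample names differ within each of these pairs. By sample name, WT replicate 3 and C59S replicate 2 alone share a number between WT and C59S, and their correlation was 0.01. The correlations were -0.09 to 0.05 between WT and C59A and -0.29 to 0.05 between C59A and C59S, where no pairing was used.

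The tests were tested on simulated data built from these libraries. In the C59A and WT setting 5.97%, 47.8% and 90.9% of genes with a true change of 1.5-fold, 2-fold and 4-fold were called, and 10 of 112 calls (8.93%) were false. In the C59S and WT setting these were 10.4%, 56.7% and 81.8%, with 9 of 112 false (8.04%). In both settings camera picked out a list of 25 genes shifted by 0.7 on the log2 scale and did not pick out an unchanged list. The simulated genes were drawn independently of each other, while real lists had estimated correlations of up to 0.8 (mitochondrial DNA genes). The simulation therefore does not show how camera performs on lists whose genes move together. Chance was further tested by regrouping the libraries, and the overlap of comparisons that share libraries by 100 simulations of unchanged groups. The codon change itself was not analysed here.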

Results

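Gene expression was measured by RNA sequencing in 9 mouse kidney libraries, 3 from wild-type (WT) mice and 3 from mice of each of the knock-in alleles C59A and C59S. Both alleles replace a cysteine codon of Nfkb1, the gene of the NF-kB precursor protein that is processed to a DNA-binding subunit, and both carry a selection cassette in an intron, per the labels. The labels call C59A the activated and C59S the inactivated form, but their sentence on DNA binding gives the reverse order, so no direction was assumed in any test. The series asks what altered NF-kB signalling does to the kidney. Total counts per library ran from 16367403 in C59A replicate 1 to 25787659 in C59S replicate 1. Mitochondrial genes took 18.3% ± 1.67 of the counts in WT, 24.8% ± 4 in C59A and 28.8% ± 10.5 in C59S (SD, n = 3 each), with C59S replicate 3 at 40.6%. The labels do not say that the replicates are separate animals, so p-values measure only the spread between these samples, which may be technical.

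The C59A libraries differed from the other 6 in their sex-linked transcripts. Ddx3y, Eif2s3y, Kdm5d and Uty, genes of the Y chromosome, were read at 43.2 to 46.9, 82 to 88.7, 17.7 to 24.8 and 18.3 to 20.2 CPM (counts scaled to library totals and TMM factors, see the processing) in the 3 C59A libraries. Xist, the RNA of the inactive X chromosome, lay at 0.191 to 0.725 CPM there, against 816 to 1280 CPM in WT and 885 to 895 CPM in C59S. C59S replicate 3 held traces of Eif2s3y (17 reads), Ddx3y (12), Uty (8) and Kdm5d (1), C59S replicate 1 held 1 to 4 reads of each of the 4 genes, and WT replicate 3 held 3 reads of Eif2s3y and 2 of Ddx3y. The labels give no sex, and no genotype held libraries of both kinds. Any difference between C59A and another genotype was therefore also a difference between libraries with and without Y-linked reads. In a principal component analysis of log2 CPM, the first component took 31.9% of the variance and set C59A (41.5 to 51.5) apart from WT (-27.6 to -8) and C59S (-38.3 to -25.5). The second component took 22.8% and ran from 55.2 in WT replicate 2 to -51.3 in C59S replicate 3.

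**Figure D1:**
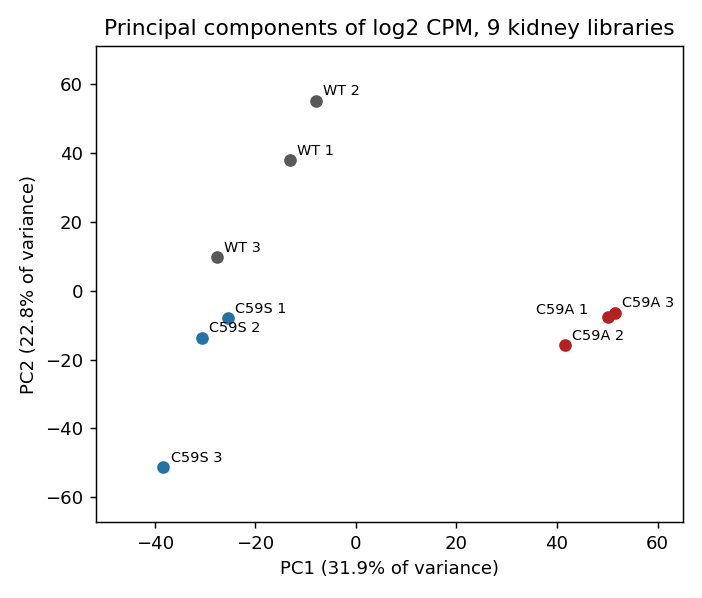
Principal components of log2 CPM for the 9 kidney libraries, 1 point per library coloured by genotype, with the share of variance on each axis. The 3 C59A libraries lie between 41.5 and 51.5 on the first component and the other 6 between -38.3 and -8.

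Nfkb1 itself (ENSMUSG00000028163, chromosome 3, 135584655 to 135691547 on the minus strand, GRCm38) was read at similar levels in all genotypes. Its CPM was 32.2, 33.8 and 36.8 in WT, 39.7, 31 and 29.2 in C59A, and 39.7, 37.5 and 36.9 in C59S. The log2 fold change against WT was -0.04 ± 0.13 (SE) for C59A and 0.15 ± 0.13 for C59S, with adjusted p of 0.896 and 0.567 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Neither passed, and the C59A value changed sign with voom (0.04). The C59S value was -0.04 with library totals alone, which moved the median of all genes to -0.19 in that comparison. Counts per gene do not show the codon change. Of the 22 members of the NF-kB and Rel family, Bcl3, a nuclear IkB protein, was higher in C59A than in WT by 0.86 ± 0.19 on the log2 scale (adjusted p = 0.0227 by the same edgeR test), and the other 21 did not pass. That call was lost without WT replicate 1 (0.069), WT replicate 3 (0.0631) or C59A replicate 1 (0.0902). Chuk, a kinase subunit of the IKK complex, was higher in C59A than in C59S by 0.81 ± 0.15 (edgeR adjusted p = 0.0117, lost without C59A replicate 1 at 0.0562 or C59S replicate 3 at 0.0597). No member passed between C59S and WT by edgeR. As a list the family was not shifted in C59A or C59S against WT or between them (camera, Benjamini-Hochberg adjusted p = 0.962, 0.716 and 0.867), and in C59A against WT its median of -0.03 and the direction of the test differed in sign.

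The first comparison asked how C59A kidneys differed from WT. The largest rises included Y-linked genes and genes of the proximal tubule known for male-biased expression, and also Mpped1 and Neurog2. Slc7a13, an amino acid transporter of the late proximal tubule (chromosome 4, 19818725 to 19842218), stood at 494 ± 37.5 CPM in C59A and 1.73 ± 0.956 CPM in WT (SD, n = 3), a log2 fold change of 8.16 ± 0.37 (SE). Slco1a1, an organic anion transporter, rose by 9.11 ± 0.57, Cyp2j13 by 6.91 ± 0.5 and Cyp7b1, an oxysterol hydroxylase, by 6.46 ± 0.5. Where WT held almost no reads, no fitted fold is given. Kdm5d was at least 451-fold, Uty at least 417-fold and Mpped1 at least 172-fold higher, against a floor of 3 counts over the WT group. Eif2s3y (ratio 1820, 95% counting interval 621 to 8810), Ddx3y (1470, 406 to 12100) and Neurog2, a proneural transcription factor gene on chromosome 3 (318, 56.7 to 12600), had 1 to 3 reads in WT.

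Among the largest falls, Atp13a4 was at least 43.6-fold lower in C59A, where it had no reads. Ugt1a2, a glucuronosyltransferase, went from 44.8 ± 24.9 CPM in WT to 0.111 ± 0.193 CPM in C59A (SD, n = 3), with log2 fold change -8.41 ± 0.95. All 7 of its C59A reads were in replicate 3, and without that library it was at least 500-fold lower, with edgeR adjusted p = 0.0269. Slc22a29 (-3.9 ± 0.24), Slc22a27 (-2.99 ± 0.51), Wfdc16 (-4 ± 0.45), the glutathione transferase gene Gsta4 (-2.86 ± 0.2) and Baat, the bile acid conjugating enzyme (-2.77 ± 0.35), also fell. Slc17a2 (-5.66 ± 1.1), the efflux pump gene Abcc3 (-3.78 ± 0.76) and Clic6 (-3.78 ± 0.79) passed with less margin. The calls of Slc17a2 and Abcc3 were lost without WT replicate 1 (adjusted p = 0.066 and 0.08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), WT replicate 2 (0.0839 and 0.0987), C59A replicate 1 (0.0803 and 0.119), C59A replicate 2 (0.104 and 0.0782) or C59A replicate 3 (0.123 and 0.128). That of Clic6 was lost without C59A replicate 1 (0.0778), 2 (0.0627) or 3 (0.0516). Members of the Ugt1a, Slc22a27 to Slc22a29 and Cyp4a12 groups are related genes that may share reads, so their single values are uncertain.

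All 10 male-biased kidney genes rose in C59A, 10 also when adjusted over the list alone, with a median log2 fold change of 5.82 (camera, adjusted p = 2.53e-18, and adjusted p = 0.0044 with an estimated correlation). Besides those above they included Cyp4a12a (5.46 ± 0.66) and Slc22a28 (2.17 ± 0.15). Kap, a protein induced by androgen, reached 26100, 37500 and 33200 CPM in C59A, against 8350, 8390 and 2940 CPM in WT. Of the 5 female-biased genes, Slc22a29 and Prlr, the prolactin receptor gene (-2.51 ± 0.32), fell and 3 did not pass (camera, adjusted p = 0.000792, and adjusted p = 0.52 with an estimated correlation). On the X and Y chromosomes, 5 of 7 tested Y genes were higher and 32 of 530 X genes passed, 13 of them higher. The sex chromosome list (4 higher, Xist lower) passed camera with adjusted p = 0.000162, and adjusted p = 0.52 with an estimated correlation.

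**Figure D2:**
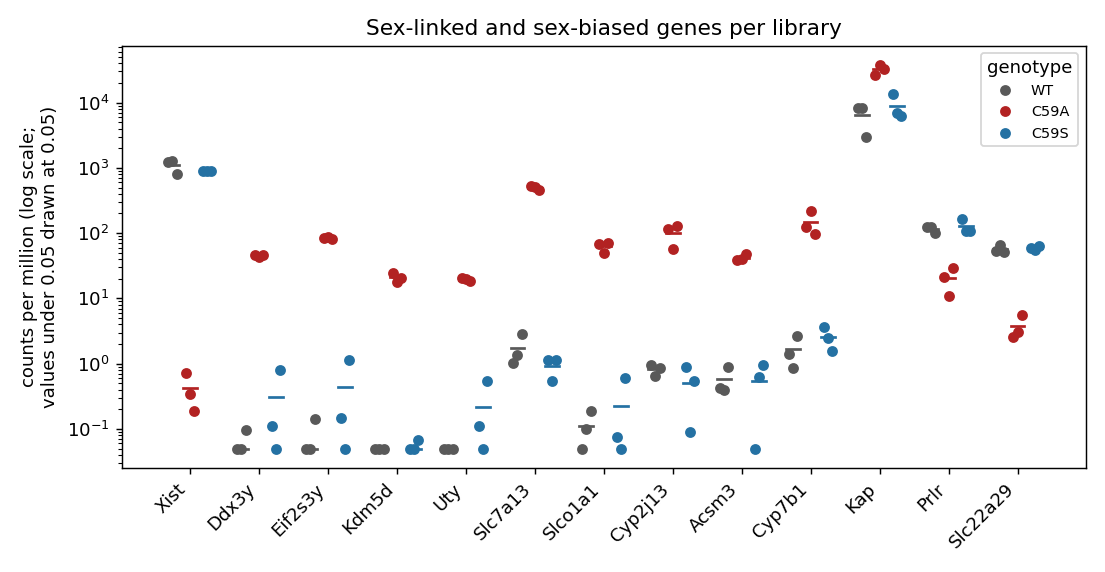
CPM on a log scale for 13 sex-linked or sex-biased genes, 1 point per library and a bar at the mean of each genotype (3 libraries each), with values under 0.05 drawn at 0.05. Slc7a13 had a mean of 494 CPM in C59A, 1.73 CPM in WT and 0.936 CPM in C59S.

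Genes of fatty acid oxidation and other PPARA targets were higher in C59A as a group. Of 33 measured, 11 rose, 2 fell and 20 did not pass (16 higher and 3 lower when adjusted over the list alone), with a median of 0.7. Cyp4a12a of this list is also on the male-biased list. Acot12, an acyl-CoA thioesterase, rose by 1.87 ± 0.19 and the fatty acid transporter gene Cd36 by 2.68 ± 0.34, while Fabp1 (-1.28 ± 0.3) and Acot3 (-1.27 ± 0.29) fell. The list passed camera with adjusted p = 7.6e-06, but had adjusted p = 0.66 with an estimated correlation. Of 27 lipid synthesis genes 23 had negative fold changes. Of these 3 fell, including Elovl6 (-1.77 ± 0.23) and Srebf2 (-0.61 ± 0.14), while Hmgcs1 (0.97 ± 0.16) rose (1 higher and 3 lower when adjusted over the list alone). That list passed camera as lower (adjusted p = 0.0283, and adjusted p = 0.66 with an estimated correlation), but not without WT replicate 2 (0.277) or C59A replicate 1 (0.139). The edgeR call of Srebf2 was lost without WT replicate 2 (0.074), C59A replicate 2 (0.0731) or C59A replicate 3 (0.079). Of 29 oxidative stress genes, 5 rose and 3 fell (9 and 4 when adjusted over the list alone). Hmox1, heme oxygenase, rose by 2.18 ± 0.24, Nqo1 by 1.13 ± 0.15 and Gclm by 1.21 ± 0.2, while Gsta4 fell. The list passed as higher (camera, adjusted p = 0.00705, and adjusted p = 0.66 with an estimated correlation), but not without C59A replicate 3 (0.0574).

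Among immune and injury genes, the neutrophil markers S100a9 (3.04 ± 0.48), S100a8 (3.36 ± 0.61) and Csf3r (1.58 ± 0.26) rose and 4 of the 7 did not pass (5 higher when adjusted over the list alone). Their list had a median of 2.68 and passed camera with adjusted p = 0.000215, and adjusted p = 0.52 with an estimated correlation. S100a8 was not called without WT replicate 1 (edgeR adjusted p = 0.0504). Of 22 kidney injury markers, Il34 (2.07 ± 0.19), a cytokine of macrophage growth, and Tnfrsf12a (1.4 ± 0.2) rose and 20 did not pass (9 higher and 1 lower when adjusted over the list alone), with camera adjusted p = 0.000515 and adjusted p = 0.65 with an estimated correlation. Havcr1 (2.47 ± 0.86) and Lcn2 (2.37 ± 0.84), the best known of them, did not pass, with edgeR adjusted p of 0.137 and 0.157. C7 (1.87 ± 0.31) and C5ar1 (1.41 ± 0.37) rose among 19 complement genes (6 higher and 3 lower when adjusted over the list alone), with camera adjusted p = 0.0283 and adjusted p = 0.66 with an estimated correlation. The complement list was lost without WT replicate 1 (0.0841) or 2 (0.0707), and the edgeR call of C5ar1 without WT replicate 1 (0.169), WT replicate 3 (0.103), C59A replicate 1 (0.134) or C59A replicate 2 (0.122). Of 34 interferon response genes, Gbp3 (-1.83 ± 0.31) and Ddx58 (-0.57 ± 0.14) fell (2 when adjusted over the list alone), with camera adjusted p = 0.0209 and adjusted p = 0.77 with an estimated correlation. The interferon list was lost without WT replicate 3 (0.442) or C59A replicate 3 (0.294), and the edgeR call of Ddx58 without WT replicate 1 (0.0732), 2 (0.0712) or 3 (0.0912) or C59A replicate 1 (0.0759) or 3 (0.115).

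Genes of nephron segments fell in several places. Of 15 podocyte genes, all with negative fold changes, Magi2 (-0.83 ± 0.16) and Nphs1, the slit diaphragm protein nephrin (-0.93 ± 0.19), fell, and 3 fell when adjusted over the list alone (camera, adjusted p = 0.00032, and adjusted p = 0.66 with an estimated correlation). The edgeR call of Nphs1 was lost without WT replicate 1 (0.066), WT replicate 3 (0.0503) or C59A replicate 3 (0.0545). Of 20 collecting duct genes, 6 fell, among them the intercalated cell genes Foxi1 (-1.05 ± 0.19), Insrr (-1.04 ± 0.17), Slc4a9 (-1.02 ± 0.18) and Atp6v1b1 (-0.98 ± 0.17), and 14 did not pass (1 higher and 8 lower when adjusted over the list alone). That list passed camera with adjusted p = 0.0283, and adjusted p = 0.66 with an estimated correlation, but not without WT replicate 3 (0.197) or C59A replicate 1 (0.162). Of 30 sodium and potassium transport genes, 6 fell and 24 did not pass (1 higher and 8 lower when adjusted over the list alone), including Klhl3 (-0.67 ± 0.12) and the thiazide-sensitive cotransporter gene Slc12a3 (-1.22 ± 0.24). The transport list had camera adjusted p = 0.0209 and adjusted p = 0.66 with an estimated correlation, and was lost without WT replicate 2 (0.0522) or C59A replicate 1 (0.0926). The edgeR call of Slc12a3 was lost without C59A replicate 1 (0.0545) and that of the collecting duct gene Slc26a4 without C59A replicate 1 (0.0549). Of 28 proximal tubule genes 6 rose and 5 fell (9 and 10 when adjusted over the list alone). As a list they were not shifted (camera, Benjamini-Hochberg adjusted p = 0.916). Their median of -0.28 and mean of 0.24 differed in sign. Slc7a13, Kap and Cyp2e1, which are also on the male-biased list, were among the rises. The mean and the list test therefore include sex-biased genes, and 16 of the 28 fold changes were negative. Slc6a19 (-1.42 ± 0.21), Slc5a2, the glucose transporter of the early segment (-1.44 ± 0.23), and Acsm1 (-1.29 ± 0.17) fell.

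Between C59A and WT, 975 of 17114 tested genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 554 of them higher and 421 lower, and 424 changed by at least 2-fold. Of the 975, 936 were autosomal. With DESeq2 1622 genes passed, with the mitochondrial share as a covariate 359 (67.1% higher, against 56.8%), and without WT replicate 1, C59A replicate 1 or C59A replicate 3 there were 530, 536 and 502. With library totals alone, which moved the median of all genes to -0.26, 1079 genes passed and 20% were higher.

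The second comparison asked how C59S kidneys differed from WT. No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while 3093 had an unadjusted p under 0.05. DESeq2 called 670 genes (261 higher, 409 lower), voom with quality weights 0 and limma on log2(FPKM + 1) 0. In a paired fit of these 6 libraries alone, with the replicate number of the titles as a block, 638 genes passed the same edgeR test with Benjamini-Hochberg adjustment (247 higher, 391 lower). This fit was added after seeing the data, and its pairs were chosen by correlations in the same libraries, so its adjusted p may be too small. The numbers in the sample names differ within each pair. Of its calls, 392 were also called by DESeq2, all with the same sign. Both fits compare the same WT and C59S libraries, so this is not independent support. The paired count was 92 without pair 1, 160 without pair 2 and 1 without pair 3, and the block gave 0 in a fit of all 9 libraries. The 5 smallest p belonged to Rac3, a small GTPase (21.2 ± 4.9 CPM in WT and 7.89 ± 0.605 in C59S), Sncg (13.9 ± 2.71 and 29.4 ± 5.02), Rpl17 (77.1 ± 8.55 and 133 ± 8.95), the potassium channel gene Kcnk5 (83.5 ± 16.3 and 40.3 ± 1.23), and Cyp27b1, the vitamin D 1-alpha-hydroxylase gene (10.2 ± 1.63 and 3.61 ± 0.205; SD, n = 3 each). Their log2 fold changes were -1.43 ± 0.18, 1.08 ± 0.17, 0.79 ± 0.13, -1.05 ± 0.17 and -1.5 ± 0.25 (SE), with adjusted p of 0.0831 for Rac3 and 0.112 for the other 4 by the same edgeR test, and of 0.0321 for each of the 5 in the paired fit. Rac3 stood at 7.72 ± 0.717 CPM in C59A as well.

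Gene lists passed camera in C59S where single genes were not called without the block. Of 10 splits of these 6 libraries, 3 passed as many lists, the real one among them, and no list passed fry. Of 42 lists, 18 lay higher and 2 lower by camera, although no list had an adjusted p under 0.59 with an estimated correlation. Endothelial genes led, with all 20 positive and a median of 0.8 (camera, adjusted p = 4.32e-09, and adjusted p = 0.59 with an estimated correlation). None of them passed over all genes and 12 passed when adjusted over the list alone, with values of 1.24 ± 0.3 for Vwf, 0.93 ± 0.22 for Pecam1 and 0.98 ± 0.24 for Cdh5. Without WT replicate 2 the endothelial median was 0.46. All 35 matrix and fibrosis genes were positive (median 0.65, adjusted p = 3.96e-08, and adjusted p = 0.59 with an estimated correlation), 5 passed when adjusted over the list alone, and Postn (3.46 ± 0.63) and Lum (2.23 ± 0.38) had the smallest p. Without C59S replicate 3 the matrix median was 0.32. The matrix level was 0.12, 0.67 and 1.2 in the C59S libraries and 0.03, -0.42 and 0.35 in WT, and Postn stood at 3.88, 19 and 25.9 CPM in C59S, so replicate 1, the C59S library with few fat transcripts, lay within the WT range of the list. Of 34 interferon response genes 30 were positive (median 0.53, adjusted p = 1.22e-07, and adjusted p = 0.59 with an estimated correlation) and 6 passed when adjusted over the list alone, with Isg15 at 1.04 ± 0.21 and Ifit1 at 0.94 ± 0.22. All 21 antigen presentation genes were positive (median 0.42, adjusted p = 2.24e-06, and adjusted p = 0.59 with an estimated correlation), 6 of them when adjusted over the list alone, with Psmb8 at 0.76 ± 0.2 and B2m at 0.64 ± 0.18. In the paired fit 7 endothelial, 5 matrix, 8 interferon and 5 antigen presentation genes passed over all genes, all higher. Among them were Vwf, Pecam1, Cdh5, Postn, Lum, Isg15, Ifit1, Psmb8 and B2m (edgeR, Benjamini-Hochberg adjusted p of 0.0351, 0.0345, 0.037, 0.0438, 0.0334, 0.0334, 0.0334, 0.0343 and 0.0398). In that fit 23 lists passed camera, all 20 of these among them, and 0 with an estimated correlation.

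The NF-kB target genes were among the lists that lay higher in C59S. Of 23 measured, 20 were positive with a median of 0.42, and none passed over all genes or when adjusted over the list alone (camera, adjusted p = 0.000922, and adjusted p = 0.59 with an estimated correlation). Csf1 (0.75 ± 0.19), C3 (1.1 ± 0.41), Mmp9 (1.42 ± 0.56) and Irf1 (0.54 ± 0.21) had the smallest p, and Csf1 alone passed in the paired fit (edgeR adjusted p = 0.0419). Without WT replicate 1 the median was 0.26. The level of the list was 0.11, 0.54 and 0.56 in the C59S libraries and -0.24, 0.06 and 0.15 in WT. C3 stood at 20.7, 61.5 and 82.9 CPM in C59S, against 23.8, 30.1 and 23 CPM in WT, so its value came from C59S replicates 2 and 3, which also held the fat transcripts given below. In C59A the same list did not pass camera. Its median was 0.11 against WT (camera adjusted p = 0.444, with a median of -0.08 with library totals alone, 0.18 relative to all genes) and -0.27 against C59S (camera adjusted p = 0.0652). The inducible nitric oxide synthase gene Nos2 was its only called member, lower in C59A than in C59S by edgeR (log2 fold change -2.03 ± 0.52, adjusted p = 0.0444), a call lost without C59A replicate 1 (0.126), 2 (0.0941) or 3 (0.0869) or C59S replicate 1 (0.0702) or 3 (0.174), and it did not pass when adjusted over the list alone. The chemokine list (median 0.51, adjusted p = 0.000179), complement (0.76, 2.6e-05), macrophage and dendritic cell (0.59, 1.44e-05) and kidney injury lists (0.55, 6.18e-05) also passed camera as higher, and each had adjusted p = 0.59 with an estimated correlation. When adjusted over the list alone, 11 complement genes were higher and 1 lower, 2 injury markers were higher, and no chemokine or macrophage gene passed. The complement list holds Cfd, which is also on the adipose list. Cfd stood at 2.24, 158 and 429 CPM in C59S and 25.9, 0.227 and 68.6 CPM in C59A. In WT it was at 0.379, 0.201 and 0.572 CPM. In the paired fit 4 complement, 2 injury and 4 macrophage genes passed over all genes. Without WT replicate 1 the macrophage median was 0.38. The proximal tubule list lay lower (median -0.32, adjusted p = 0.00312, and adjusted p = 0.67 with an estimated correlation), with 6 genes lower when adjusted over the list alone and Slc5a12 at -1.73 ± 0.38, Slc5a2 at -1.06 ± 0.23 and Slc6a19 at -0.85 ± 0.2. Slc5a2 and Slc6a19 passed in the paired fit (edgeR adjusted p = 0.0438 and 0.0419), and the median was -0.17 without C59S replicate 1. The sodium and potassium transport list was lower too (median -0.25, adjusted p = 0.00526, and adjusted p = 0.59 with an estimated correlation), with no gene passing when adjusted over the list alone, and was lost without WT replicate 3 (0.057) or C59S replicate 3 (0.0538). Its median was -0.08 without WT replicate 2, -0.07 without WT replicate 3 and -0.16 without C59S replicate 3, and 4 of its genes were lower in the paired fit.

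**Figure D3:**
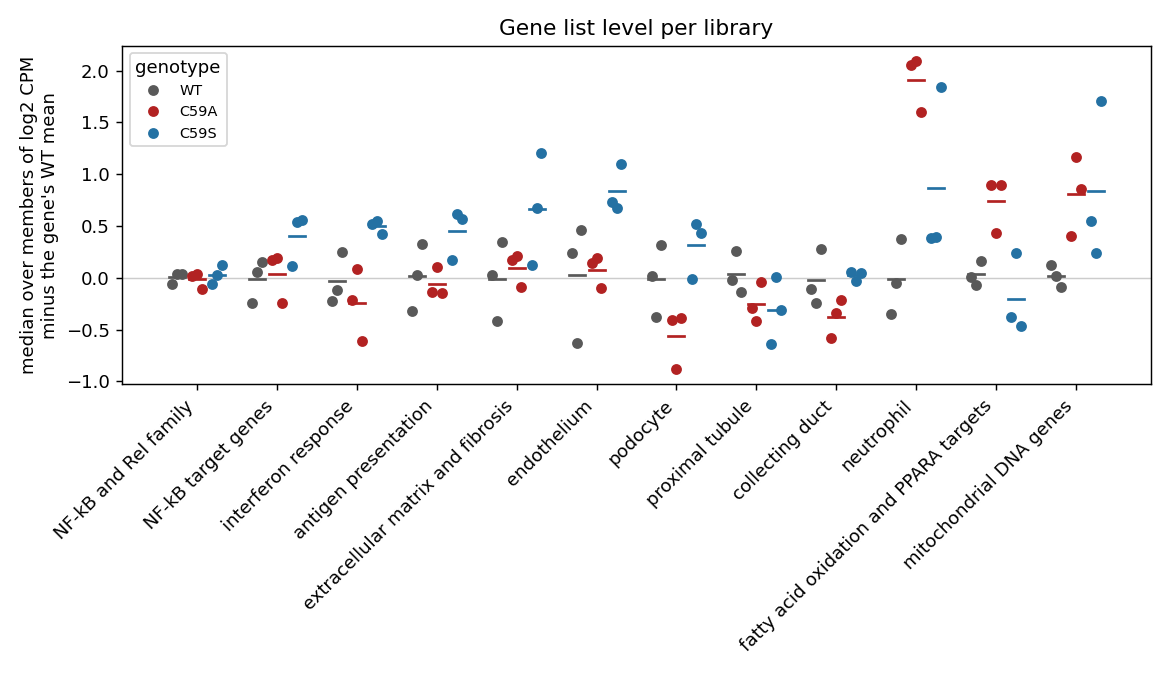
Median over the members of 12 gene lists of log2 CPM minus the WT mean of the gene, on a linear axis, 1 point per library and a bar at the mean of each genotype (3 libraries each). Endothelial genes lie at 0.67 to 1.1 in C59S and at -0.63 to 0.46 in WT.

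Fat genes and mitochondrial genes also differed between the libraries. Adipoq, the adipocyte hormone adiponectin, was at 0.224, 42.3 and 39.8 CPM in C59S, 4.05, 0.17 and 15.8 CPM in C59A, and 0, 0.0503 and 0.0477 CPM in WT. In C59S replicate 1, with the least of it, the levels of the matrix, antigen presentation, macrophage and NF-kB target lists lay within the WT range, and those of the endothelial, interferon, complement, chemokine and injury lists above it. In reads, C59S held 776 times the Adipoq of WT (95% counting interval 214 to 6410), from 2 reads in WT. The 16 adipose genes were all positive in C59S against WT with a median of 2.84, 12 of them passing when adjusted over the list alone, none over all genes and 1 in the paired fit (camera, adjusted p = 1.42e-07, and adjusted p = 0.59 with an estimated correlation). The same list was higher in C59A (median 1.53, adjusted p = 0.000548, and adjusted p = 0.66 with an estimated correlation), with no gene called there on either adjustment. The 13 genes of mitochondrial DNA were positive in both mutants (medians 0.98 in C59S and 0.84 in C59A; adjusted p = 2.26e-05 and 0.000162, and adjusted p = 0.59 and 0.66 with an estimated correlation). When adjusted over the list alone 1 of them passed in C59S and 2 in C59A. Over all genes mt-Nd3 passed in C59A (edgeR adjusted p = 0.0406), lost without WT replicate 1 (0.0955), 2 (0.123) or 3 (0.106) or C59A replicate 1 (0.111) or 2 (0.0933), and none in C59S, where mt-Atp6 passed in the paired fit (0.0321). The C59S median rested on replicate 3, without which it was 0.33, and the level of the list was 0.55, 0.24 and 1.71 in the 3 C59S libraries. The ribosomal protein list lay higher in C59S by a median of 0.16 (adjusted p = 9.87e-05, and adjusted p = 0.71 with an estimated correlation), but by -0.04 with library totals alone, which moved the median of all genes to -0.19. It was 0.1 without WT replicate 1 or 2 and 0.32 without WT replicate 3. None of its genes passed when adjusted over the list alone.

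**Figure D4:**
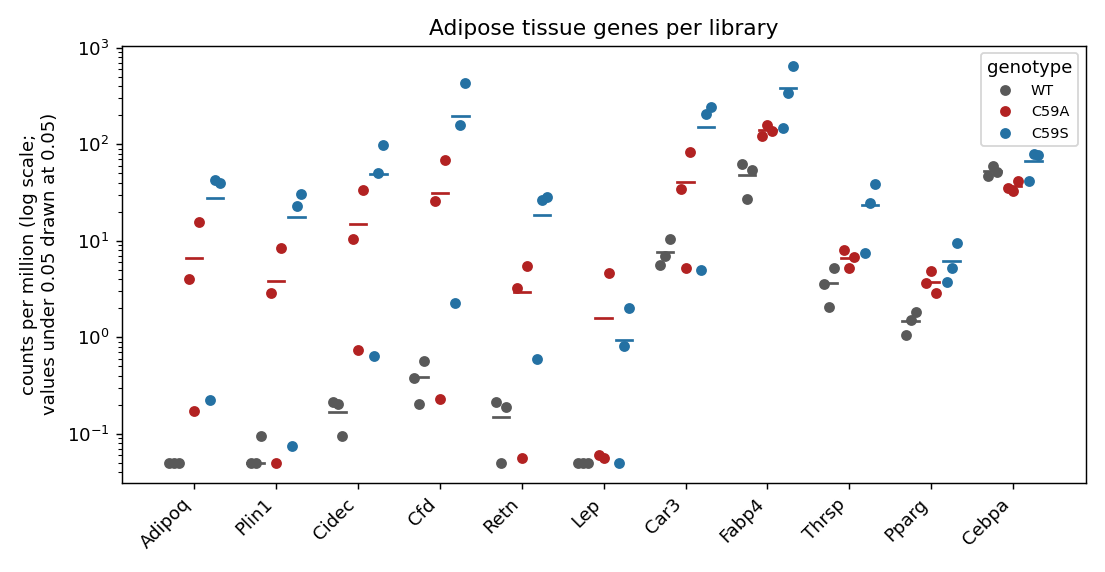
CPM on a log scale for 11 genes of the adipose list, 1 point per library and a bar at the mean of each genotype (3 libraries each), with values under 0.05 drawn at 0.05. Adipoq lies at 42.3 and 39.8 CPM in C59S replicates 2 and 3 and at 0.224 CPM in C59S replicate 1.

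The count of 0 between C59S and WT depended on single libraries. It was 737 (220 higher, 517 lower) without WT replicate 3, 33 without C59S replicate 1 and 1 without C59S replicate 2, and 308 when every gene with at least 1 read was tested. With C59S replicates 2 and 3, the libraries with most fat transcripts, both left out, a choice made after seeing the data, 1 gene passed.

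The third comparison set the 2 knock-in alleles against each other. Among the genes with the largest rises in C59A were again Y-linked and male-biased ones, and also Neurog2 and Mpped1, with Slc7a13 at 9.05 ± 0.39, Slco1a1 at 8.44 ± 0.54, Cyp2j13 at 7.57 ± 0.53, Acsm3 at 6.45 ± 0.53, Eif2s3y at 7.92 ± 0.66, Ddx3y at 7.51 ± 0.6 and Uty at 6.72 ± 0.61 (log2 fold change ± SE). C59S replicate 3 held 17 of the 21 C59S reads of Eif2s3y, 12 of 15 of Ddx3y and 8 of 11 of Uty. Slco1a1 had 2, 0 and 9 reads in the C59S libraries, so the folds of these 4 genes rest on few reads, mostly from 1 library. Neurog2 was at least 105-fold higher, and Kdm5d (ratio 668, 95% counting interval 184 to 5520) and Mpped1 (511, 91.2 to 20200) had 2 reads and 1 read in C59S. Lower in C59A were Ugt1a2 (-7.28 ± 0.97, and at least 223-fold lower without C59A replicate 3), Dfnb59 (-4.37 ± 0.6), Slc22a29 (-3.98 ± 0.24), Wfdc16 (-3.78 ± 0.45), Scgb1c1 (-2.87 ± 0.51), Prlr (-2.64 ± 0.33) and, with 2 reads in C59A, the myosin gene Myh1 (ratio 64.5, 17.5 to 537). The growth factor gene Igf2 had 3.16 ± 0.163 CPM in C59A and 132 ± 95.2 CPM in C59S (SD, n = 3), and its edgeR call at adjusted p = 0.0396 was lost without any 1 of the 6 libraries, up to 0.144 without C59A replicate 3. The calls of Slc17a2 (-6.21 ± 1.1) and Abcc3 (-3.98 ± 0.76) were lost without C59A replicate 1 (edgeR adjusted p = 0.0763 and 0.117), 2 (0.0714 and 0.0603) or 3 (0.101 and 0.115), and that of Abcc3 also without C59S replicate 1 (0.0652) or 2 (0.0804). Those of Scgb1c1 (0.0513) and Myh1 (0.0747) were lost without C59A replicate 3, and that of Myh1 also without C59A replicate 1 (0.0737).

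All 10 male-biased genes were higher in C59A than in C59S (median 5.73, camera adjusted p = 2.34e-17, and adjusted p = 0.0051 with an estimated correlation), also when adjusted over the list alone. Slc22a29 and Prlr were the female-biased genes that fell, over all genes and when adjusted over the list alone (camera, adjusted p = 0.0012, and adjusted p = 0.49 with an estimated correlation). The sex chromosome list had 4 genes higher and Xist lower, the same numbers when adjusted over the list alone (adjusted p = 0.000302, and adjusted p = 0.49 with an estimated correlation). Of 33 fatty acid oxidation genes 11 rose and 1 fell (20 and 1 when adjusted over the list alone), including Acot12 (2.26 ± 0.19) and Pex11a (1.19 ± 0.18), with camera adjusted p = 3.44e-08 and adjusted p = 0.56 with an estimated correlation. Of 29 oxidative stress genes 4 rose, including Nqo1 (1.47 ± 0.15) and Hmox1 (2 ± 0.24), and 2 fell, including Gsta4 (-2.4 ± 0.19; 6 higher and 3 lower when adjusted over the list alone). That list passed camera at adjusted p = 0.0395, and adjusted p = 0.77 with an estimated correlation, but not without C59A replicate 1 (0.0556), C59A replicate 3 (0.262) or C59S replicate 1 (0.317). By edgeR, Gclm was lost when any 1 of 4 libraries was left out, up to 0.0877 without C59S replicate 3. Among 27 lipid synthesis genes Elovl6 (-2.29 ± 0.23) and Fdft1 (-0.76 ± 0.17) fell and Hmgcs1 (0.82 ± 0.16) rose (1 higher and 10 lower when adjusted over the list alone), with camera adjusted p = 0.0379 and adjusted p = 0.77 with an estimated correlation. The lipid synthesis list was lost without C59A replicate 1 (0.123) or C59S replicate 3 (0.086). By edgeR, Fdft1 was lost without C59A replicate 1 (0.103) or 3 (0.106) or C59S replicate 2 (0.0657) or 3 (0.112), and Hmgcs1 without C59A replicate 3 (0.0542) or C59S replicate 2 (0.0653) or 3 (0.0731).

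Interferon and antigen presentation genes passed as lists with lower values in C59A than in C59S. Of 34 interferon genes 33 were negative with a median of -0.7, 7 fell and 22 fell when adjusted over the list alone (camera, adjusted p = 4.56e-11, and adjusted p = 0.49 with an estimated correlation). They included Gbp3 (-2.52 ± 0.32), Isg15 (-1.24 ± 0.22), Bst2 (-0.97 ± 0.18) and Irf7 (-0.8 ± 0.16). By edgeR, Bst2 was lost without C59A replicate 3 (0.0504) or C59S replicate 3 (0.0588), and Irf7 without C59A replicate 1 (0.0623) or 3 (0.0656) or C59S replicate 3 (0.0645). Of 21 antigen presentation genes 6 fell and 11 fell when adjusted over the list alone (median -0.47, camera adjusted p = 4.34e-06, and adjusted p = 0.65 with an estimated correlation), with the near-identical copies H2-Q6 (-1.28 ± 0.2) and H2-Q7 (-0.92 ± 0.15) as the smallest p. By edgeR, Tap2 and Psmb10 among them were each lost when any 1 of 4 libraries was left out, up to 0.116 and 0.138 without C59S replicate 3. The 15 podocyte genes were all negative with a median of -0.86, 5 fell and 13 fell when adjusted over the list alone (adjusted p = 1.76e-07, and adjusted p = 0.49 with an estimated correlation), including the cell cycle inhibitor gene Cdkn1c (-1.11 ± 0.2) and Nes (-1 ± 0.18). By edgeR, Nes was lost without C59S replicate 3 (0.053), and Cdkn1c without C59S replicate 3 (0.0508) or C59A replicate 1 (0.0555). Magi2 and Nphs1 were each lost when any 1 of 3 libraries was left out, up to edgeR adjusted p = 0.0656 and 0.0634 without C59S replicate 2. Apln, the gene of the vasoactive peptide apelin, fell by 1.69 ± 0.24, and the vasoactive list had 4 genes lower and 1 higher on both adjustments (adjusted p = 0.000398, and adjusted p = 0.49 with an estimated correlation). Of these, Aplnr was lost when any 1 of 4 libraries was left out (edgeR adjusted p up to 0.0709 without C59S replicate 3).

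The 20 endothelial genes all had negative fold changes in C59A against C59S (median -0.73, camera adjusted p = 4.37e-06, and adjusted p = 0.65 with an estimated correlation), with 3 falling and 7 when adjusted over the list alone. Pecam1 (-0.92 ± 0.22), Cdh5 (-0.95 ± 0.24) and Cldn5 (-0.95 ± 0.23) had edgeR adjusted p of 0.0396, 0.0478 and 0.0364, and each lost its call without C59A replicate 1 (0.103, 0.146 and 0.14), 2 (0.0721, 0.0759 and 0.0745) or 3 (0.151, 0.17 and 0.104) or C59S replicate 2 (0.0762, 0.0817 and 0.0966) or 3 (0.143, 0.158 and 0.136). Matrix genes (median -0.59, camera adjusted p = 0.000211), B and plasma cell genes (-0.9, 0.0012), collecting duct genes (-0.42, 0.00146) and fibroblast and smooth muscle genes (-0.58, 0.00175) also passed as lower, with adjusted p = 0.77, 0.65, 0.65 and 0.77 with an estimated correlation. They held 2, 0, 2 and 1 genes that fell, and 2, 0, 6 and 0 when adjusted over the list alone. By edgeR, the matrix gene Lum was lost without C59A replicate 1 (0.0955) or 3 (0.0746) or C59S replicate 2 (0.0838) or 3 (0.0869), and Tgfb2 without any library but C59S replicate 1 (0.134, 0.0547, 0.0906, 0.0656 and 0.139). The collecting duct gene Foxi1 was lost without C59A replicate 1 (0.0939) or C59S replicate 2 (0.0824) or 3 (0.093), and Insrr without C59A replicate 1 (0.134) or 2 (0.0751) or C59S replicate 1 (0.0891) or 3 (0.106). The pericyte gene Rgs5 was lost without any library but C59S replicate 1 (edgeR adjusted p of 0.136, 0.0937, 0.17, 0.0856 and 0.119). T and NK cell genes (-0.47, 0.0239, and adjusted p = 0.77 with an estimated correlation) and skeletal muscle genes (-0.55, 0.0362, and adjusted p = 0.49 with an estimated correlation) passed as lower, with 0 and 2 genes falling on either adjustment. Pvalb, which is also on the distal tubule list, was lost when any 1 of 4 libraries was left out (edgeR adjusted p up to 0.116 without C59A replicate 1). Without C59S replicate 3 the fibroblast list (median -0.29, 0.0531) and the T and NK cell list (-0.18, 0.371) did not pass, and the matrix and B cell medians were -0.37 and -0.57. The B cell median was -1.7 without C59A replicate 2. Without C59A replicate 3 the T and NK cell list (0.072) and without C59A replicate 2 the skeletal muscle list (-0.84, 0.0604) did not pass, and the skeletal muscle median was -1.36 without C59A replicate 3. Neutrophil genes were higher (1.57, 0.00945, and adjusted p = 0.63 with an estimated correlation), with 2 genes rising and 3 when adjusted over the list alone. By edgeR, S100a9 was lost without C59A replicate 1 (0.0828) or 3 (0.0918) or C59S replicate 1 (0.0691) or 2 (0.0982), and Csf3r without C59A replicate 1 (0.149) or 2 (0.0684) or C59S replicate 1 (0.0961), 2 (0.0991) or 3 (0.106). C59S replicates 2 and 3 carried the fat transcripts described above.

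Between C59A and C59S, 1012 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 574 higher and 438 lower in C59A, and 452 differed by at least 2-fold. Of these, 976 were autosomal. DESeq2 called 1765 genes, voom with quality weights 1768 and library totals alone 670 (47% higher, against 56.7%). Without C59A replicate 1 the count was 370, without C59A replicate 3 it was 405, without C59S replicate 2 it was 433 and without C59S replicate 3 it was 318. With C59S replicates 2 and 3 both left out it was 125.

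A test over all 3 genotypes at once called 1150 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 5 named genes with the smallest p were Slc7a13, Pank1, Kdm5d, Slc22a28 and Ftcd. Pank1, a pantothenate kinase of coenzyme A synthesis, stood at 226 ± 6.81 CPM in C59A, 48.3 ± 2.3 CPM in WT and 52 ± 4.49 CPM in C59S (SD, n = 3 each). Ftcd, an enzyme of histidine breakdown, stood at 63.1 ± 5.1, 17.6 ± 4.07 and 11 ± 0.297 CPM. Their adjusted p were 7.21e-07 and 1.39e-05 by the same edgeR test. The count was 428 without C59A replicate 1, 486 without C59A replicate 3, 670 without WT replicate 1, 729 without C59S replicate 2, 580 without C59S replicate 3 and 1882 without WT replicate 3.

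The lists of genes called in C59A against WT and against C59S overlapped. They shared 351 genes higher and 186 lower in C59A, none in opposite directions, against 18.6 and 10.8 for independent lists. The lists are not independent, since both comparisons use the same C59A libraries. Both also set libraries with Y-linked reads against libraries with almost none. An overlap in the same direction was thus built into the design and does not show an effect of the allele. In 100 simulated pairs of groups that shared the C59A libraries 0.04 genes were shared on average, but no gene was changed there, so this count sets no expected overlap for lists of this length. The fold changes of the 2 comparisons correlated across genes with r = 0.67, against 0.51 in the simulations, and their covariance was 0.313, against 0.0663. Genes are not independent replicates, and part of the excess may come from the shared libraries, since a group of 3 libraries cannot be divided into 2 groups of 2. Between the 2 mutants set against WT no gene was shared by edgeR, where C59S had no calls, while DESeq2 gave 163 shared genes. The paired C59S fit shared 70 genes with C59A against WT in the same direction and 3 in the opposite one. Both comparisons use the same WT libraries, which favours the same direction, so these counts do not show changes common to both alleles. The correlation across genes was 0.42, against 0.49 in the simulations (0.45 to 0.54), and the covariance 0.162, against 0.0636 (0.0575 to 0.0708). With the simulated WT and C59S libraries paired as observed, these were 0.43 (0.4 to 0.47) and 0.0477 (0.0434 to 0.0537). The shared count was 160 without WT replicate 3, 10 without C59S replicate 1 and 1 without C59S replicate 2.

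Genes near Nfkb1 were examined because the alleles were made in C57BL/6N-derived cells. Of 111 tested genes within 10 Mb, 12 were called between C59A and WT, among them Gbp3, Elovl6, Neurog2, Adh1, Adh7 and Ugt8a, which was 10.8% against 5.66% elsewhere (two-sided Fisher's exact test, p = 0.0354). Between C59A and C59S it was 13 of 111, or 11.7% against 5.88% (Fisher's exact test, p = 0.023), and none was called by edgeR between C59S and WT (6 of 102 in the paired fit, Fisher's exact test, p = 0.29). Within 2 Mb it was 1 of 19 in both comparisons with C59A (Fisher's exact test, p = 1), and within 30 Mb it was 21 and 22 of 298 (Fisher's exact p = 0.312 and 0.265). Of the 5 tested substrain genes none passed in any comparison by edgeR, and in C59A against C59S 2 were higher when adjusted over the list alone.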

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

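The predictions for the splits of the libraries and for the segment near Nfkb1 were written before their results were seen, and all other tests in this part were chosen after the result was seen.

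The results listed next stood out by a test of the difference between the alleles. The change against WT differed between C59A and C59S for 1012 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the same test as the direct comparison of the alleles. Among them were all 10 male-biased kidney genes, led by Slc7a13. All C59A libraries held Y-linked reads and the C59S libraries almost none, so this test could not separate the alleles from sex. Groups of 3 libraries were not tested for outliers.

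Regrouping the libraries tested how often unrelated groups give as many calls. Between C59A and WT 1 of 10 splits, the real one, gave as many as 975 genes, with 1 gene as the highest other count. Between C59A and C59S 1 of 10 gave as many as 1012, with 0 as the highest other, and between C59S and WT 10 of 10 gave at least 0, with 0 as the highest other. With 10 splits there are too few for a share under 0.05. Over all 3 genotypes 1 of 100 partitions, the real one, gave as many as 1150, with 556 as the highest other, which argued against an arbitrary grouping of the libraries. The other partitions with 364 to 556 calls all kept the 3 C59A libraries together, and the rest gave at most 24. The count thus largely reflects C59A lying apart, which also parts libraries with and without Y-linked reads. It does not show that all 3 genotypes differ. For the gene lists 3 of 10 splits passed as many as 17 in C59A against WT (highest other 19), 3 of 10 as many as 20 in C59S against WT (20), and 4 of 10 as many as 18 in C59A against C59S (26). With the title numbers as pairs, the real split of C59S and WT gave 638 called genes by edgeR with the block, and the 3 other splits that part all 3 pairs gave 0 each. These 4 splits are too few for a share under 0.05. The 5 other ways to pair the 6 libraries gave 0 to 4 called genes. The title pairing was chosen because its correlations in these data were 0.2 to 0.32. Each other pairing held a negative one (lowest -0.25 to -0.13), so their lower counts are no support for the pairing.

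The first pattern weighed was that the C59A libraries, with Y-linked reads, lay apart from WT and C59S. A sex difference fitted the sex-biased genes, since 10 of 10 male-biased genes including Slco1a1 and Cyp2j13 rose. Whether it could also explain the other 926 called genes, outside the sex lists and off X and Y, could not be told, because no genotype held both kinds of library. The male-biased and female-biased lists hold only 10 and 5 genes, so the 926 are not a count of genes without sex bias. Of the 975 called genes 12 lay within 10 Mb of Nfkb1, so the prediction that most of them lie there was not met. With only 111 tested genes in that window it could not have been met. Effects of a linked segment on distant genes were not tested, so such a segment was not excluded. An effect of the C59A allele on these 926 genes remains possible and was not separable from sex.

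The second pattern was fat genes in some libraries. In the 4 libraries with Adipoq above 1 CPM, the ratios of other fat genes to Adipoq spread by a median of 2.26 while Adipoq itself spread by 10.4, as fat tissue taken along with the kidney may give. Only 5 genes were compared, and the ratio of Lep spread by 19.8. Of 16 adipose genes 10 had at least 1 CPM in WT kidney. A genotype effect could not be told, since the exact permutation p of the list level between C59S and WT was 0.1, the smallest that 3 against 3 libraries allow, and C59S replicate 1 held 0.224 CPM of Adipoq.

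The third pattern was the rise of many lists in C59S against WT. A lower share of proximal tubule cells would raise all other cell types alike, but the endothelial median exceeded that of 38 genes of the other tubule segments by 0.76 (bootstrap interval 0.57 to 0.95 over genes). That interval holds no spread between libraries and takes genes as independent, while the endothelial genes had an estimated correlation of 0.76. The endothelial median itself went from 0.8 to 0.46 without WT replicate 2. A lower share was therefore not excluded as the whole cause. A gradient between libraries could not be told. Within genotypes the lincRNA share and the mean level of 17 raised lists had r = -0.8 (exact permutation p = 0.0694, Spearman rho -0.78 with exact p = 0.0787, 9 libraries), but r = -0.43 without C59S replicate 3 and WT replicate 3, the 2 farthest libraries. The permutations took libraries as unpaired. Yet WT and C59S replicates 1 deviated in the same direction in both measures, as did replicates 3, and replicates 2 did so only in the lincRNA share. An effect of the C59S allele was not excluded, and without the block no gene passed edgeR with or without that share as a covariate.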

How the results depend on the processing

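The alternatives marked as added (mitochondrial, adipose or lincRNA share as covariate, C59S replicates 2 and 3 left out, X and Y left out, the paired fit) were chosen after seeing the data, and the others before the data were examined. No called named gene changed direction under any of them. Of 60 named calls between C59A and WT 20 were lost with the mitochondrial share and 34 with a block by sample name number, and of 64 between C59A and C59S 15 and 41. In the block by sample name number, WT replicate 1 and C59S replicate 1 share their number with no other library. These libraries therefore add nothing to the comparisons there, and less is left to estimate the spread. The losses and lower counts with that block are thus no evidence of a batch. The causes of the changes below were not tested, except where fewer libraries or another threshold make them.

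The 975 genes called between C59A and WT became 1622 with DESeq2, 128 with a block by sample name number, 475 with log2(FPKM + 1) and every gene above 0, and 359 with the mitochondrial share (added). They were 424 at an absolute log2 fold change of at least 1 and 1679 at adjusted p under 0.1, and 17 of 23 settings stayed within 1.5 times. Leaving out 1 library gave 502 (without C59A replicate 3) to 852 (without WT replicate 3). Of the 975 calls, 467 to 672 were kept and none changed sign.

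Between C59S and WT the 0 became 20 with library totals alone, 308 with every gene with at least 1 read, 670 with DESeq2, 2 with log2(FPKM + 1) and every gene above 0, 1 with C59S replicates 2 and 3 left out (added), 638 in the paired fit (added) and 1 at adjusted p under 0.1. Where C59S held 1 library, it was assumed to vary like the other groups. Leaving out 1 library gave 0 to 737 (without WT replicate 3).

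Between C59A and C59S the 1012 became 670 with library totals alone, 1765 with DESeq2, 1768 with voom with quality weights, 118 with a block by sample name number, 663 with log2(FPKM + 1), 670 with log2(FPKM + 0.1) and 311 with every gene above 0. The mitochondrial share gave 552 and C59S replicates 2 and 3 left out 125 (both added), an absolute log2 fold change of at least 1 gave 452 and adjusted p under 0.1 gave 1816. Leaving out 1 library gave 318 (without C59S replicate 3) to 1006 (without C59A replicate 2).

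Over 3 genotypes the 1150 became 1880 with every gene with at least 1 read, 2629 with DESeq2, 133 with a block by sample name number, 665 with log2(FPKM + 1), 679 with log2(FPKM + 0.1), 351 with every gene above 0, 510 with the mitochondrial share, 462 with C59S replicates 2 and 3 left out (the last 2 added), 542 at an absolute log2 fold change of at least 1 and 2335 at adjusted p under 0.1. Leaving out 1 library gave 428 to 1882. The 0 genes shared by both mutants against WT became 8 with library totals alone, 70 with every gene with at least 1 read, 163 with DESeq2, 1 with C59S replicates 2 and 3 left out and 1 at adjusted p under 0.1, and 0 to 160 with 1 library left out.

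The log2 fold change of Nfkb1 between C59A and WT was 0.04 with voom and 0.04 with the mitochondrial share (added), against -0.04, and -0.18 to 0.05 with 1 library left out. Between C59S and WT it was -0.04 with library totals alone, against 0.15, and 0.11 to 0.21 with 1 library left out, and between C59A and C59S -0.33 to -0.11.

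Of the lists, 17, 20 and 18 passed in the 3 comparisons, against 1, 0 and 1 with an estimated correlation and 5, 0 and 8 with fry. With 1 library left out they were 15 to 22, 15 to 24 and 16 to 22. The excess of called genes near Nfkb1, 5.15 and 5.84 percentage points within 10 Mb, was -0.434 and -0.651 within 2 Mb and 1.37 and 1.5 within 30 Mb.

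A block for the replicate number of the titles gave 1004, 0, 972 and 1143 called genes. Over all 9 libraries 5 had their closest partner under the same number. In the paired fit of C59S and WT alone, Nfkb1 was at 0.14 and 23 lists passed camera. Beyond the calls given beside the results, the paired fit changed no other call between C59S and WT given here.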

Other observations

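The hypotheses in this part were formed and their tests chosen after the results were seen.

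Some gene groups outside the main results also moved. In C59A against WT, the macrophage and dendritic cell list lay higher (median 0.29, camera adjusted p = 0.0249, and adjusted p = 0.78 with an estimated correlation) and the circadian clock list lower (-0.22, 0.0418, and adjusted p = 0.66 with an estimated correlation). The integrin gene Itgam and the clock regulator Bhlhe40 (-0.8 ± 0.17) were the only called members, and 1 and 4 genes passed when adjusted over the list alone. The macrophage list was lost without WT replicate 1 (0.379) or C59A replicate 2 (median 0.07, 0.209) and had 0.59 without WT replicate 3. The clock list had -0.51 without C59A replicate 2 and was lost without WT replicate 1 (0.0841), WT replicate 2 (0.0522), C59A replicate 1 (0.129) or C59A replicate 3 (0.0883). Each of the 2 gene calls was lost without 4 or more of the libraries, up to edgeR adjusted p = 0.0942 for Itgam and 0.0698 for Bhlhe40. The renin-angiotensin list passed in no comparison (camera, Benjamini-Hochberg adjusted p = 0.444, 0.553 and 0.169 for C59A against WT, C59S against WT and C59A against C59S).

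In C59S against WT, 6 further lists passed camera as higher without a called gene. Fibroblast and smooth muscle genes had a median of 0.7 (adjusted p = 0.0017, and adjusted p = 0.67 with an estimated correlation), with the actin-binding protein gene Gsn at 1.2 ± 0.27. T and NK cell genes had 0.39 (0.0113, and adjusted p = 0.7 with an estimated correlation), vasoactive genes 0.25 (0.0133, and adjusted p = 0.59 with an estimated correlation) and podocyte genes 0.33 (0.0244, and adjusted p = 0.71 with an estimated correlation). Apoptosis genes had 0.23 (0.0323, and adjusted p = 0.59 with an estimated correlation), with Phlda3 at 1.26 ± 0.28 (edgeR adjusted p = 0.0321 in the paired fit), and neutrophil genes 1.06 (0.0323, and adjusted p = 0.59 with an estimated correlation). When adjusted over the list alone 1 fibroblast, 1 podocyte and 2 apoptosis genes passed, and no T cell, vasoactive or neutrophil gene did. In the paired fit 2 apoptosis genes, 1 podocyte gene and 1 vasoactive gene were higher over all genes and 1 vasoactive gene was lower. The fibroblast list was lost without WT replicate 2 (median 0.41, 0.0804) and had 0.36 without C59S replicate 3. Its level was 0.11, 0.63 and 1.13 in the C59S libraries, where the adipose list stood at 0.39, 2.87 and 3.66, and -0.02, -0.42 and 0.44 in WT. The T and NK cell list was lost without WT replicate 1 (0.125) or C59S replicate 3 (0.12, 0.332) and had 0.62 without C59S replicate 1. The vasoactive list was lost without WT replicate 2 (0.12, 0.132) and had 0.52 without WT replicate 3. The podocyte list was lost without WT replicate 2 (median 0.09, 0.444) or C59S replicate 2 (0.13, 0.134) or 3 (0.0544), and had 0.64 without WT replicate 3 and 0.52 without C59S replicate 1. The apoptosis list was lost without WT replicate 1 (0.107) or C59S replicate 3 (0.0721), and the neutrophil list without WT replicate 1 (0.0956) or 2 (0.0737) or C59S replicate 3 (median 0.42, 0.207).

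Other lists passed camera in no comparison. The adjusted p for C59A against WT, C59S against WT and C59A against C59S were 0.0663, 0.616 and 0.215 for nuclear genes of oxidative phosphorylation, 0.929, 0.612 and 0.948 for glycolysis, 0.165, 0.0795 and 0.794 for immediate early and heat shock genes, and 0.806, 0.0574 and 0.236 for the unfolded protein response. They were 0.377, 0.462 and 0.953 for the cell cycle, 0.112, 0.675 and 0.236 for the loop of Henle and distal tubule, 0.0983, 0.245 and 0.43 for erythroid genes, 0.861, 0.553 and 0.305 for adrenal genes, 0.991, 0.839 and 0.824 for liver and pancreas genes, and 0.962, 0.418 and 0.498 for substrain genes (camera, Benjamini-Hochberg adjustment). In the paired fit of C59S and WT the unfolded protein response (camera adjusted p = 0.0399), erythroid (0.0455) and B and plasma cell lists (0.0343) passed as higher, with medians of 0.13, 0.41 and 0.42, and no list passed with an estimated correlation (smallest adjusted p = 0.62).

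A first hypothesis was that the alleles move expression in opposite directions. The covariance of the fold changes against WT exceeded that of simulated unchanged groups by 0.098, with a jackknife error of 0.11, and by 0.11 where the simulated WT and C59S libraries were paired as observed, which could not tell opposite from shared changes.

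A second hypothesis was that C59A raises and C59S lowers the NF-kB target genes. The median log2 fold change of the targets between C59A and C59S was -0.27 (bootstrap interval -0.47 to 0.02 over genes), with an exact permutation p of 0.3 across libraries. The exact permutation p was 0.2 for C59S against WT and 0.6 for C59A against WT, and within the 3 pairs of C59S and WT the list differed by 0.34, 0.48 and 0.41 (exact permutation p = 0.25, the smallest that 3 pairs allow), so the data could not tell.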
